A study of Mus musculus with 4 samples.

How the data were processed

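The data are 2-colour oligonucleotide array ratios from cultured mouse small intestinal epithelium. Per the labels' protocols, intestine of single CD1 wild-type animals was grown in Matrigel, a basement membrane gel, with EGF, Noggin and R-spondin1. These factors sustain growth, block BMP signalling and raise Wnt signalling. Such cultures held spheroids, which are round hollow epithelial cysts, and organoids, which bud into crypt-like structures. Each type was picked and replated for 3 passages, per the labels, before RNA was taken. Amplified antisense RNA was labelled with Cy3 or Cy5 and hybridised to arrays of 70-base probes (MEEBO), spheroid against organoid of the same animal. Each animal's pair was hybridised with the dyes swapped, per the design text.

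As deposited by the authors, the values are taken as log2 ratios, 1 per probe and animal for 38083 probes. How the dye orientations were combined is not given in the sources used here. All values were whole multiples of 0.0005, as the mean of 2 arrays given to 3 decimals would be. Background correction, normalization and any filter are not given in the sources used here. The unit was taken as log2, the usual base of scanner ratios, which no label states. A log10 ratio was set aside because values reached 7.51, beyond what a 16-bit scanner can record on that scale. The column medians were -0.001 for the P0 pair, -0.004 and -0.0055 for the E16 pairs and -0.003 for the E18 pair, so the columns were already centred, by a method that stays unknown. No label names the numerator. The deposited sign was kept and a positive value is read as likely spheroid over organoid, because the titles name the spheroid first and the first channel is the spheroid. All columns correlated positively with each other, so they run the same way. If the sign were the other way round, each direction given for spheroids would turn. No value was missing, and no intensities were used here, so the number of arrays limits the precision and brightness over background is unknown.

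Probes were named through GEO's platform annotation, which can be old. It gives 1 gene for 22941 probes, several genes for 0 probes and none for 15142 probes, which are unnamed here. All 22941 named probes had a gene ID found in the RefSeq gene table of assembly GRCm38.p6, used for symbols only. The 3005 control, transgene and viral probes, told by their ID prefix, were left out of the tests, 636 of which name a gene. The other 22305 named probes were averaged to 15123 genes. Of the 5108 genes with more than 1 probe, 99 had probe means more than 1 log2 unit apart. The 94 probes with a negative control prefix had mean log2 ratios from -0.16 to 0.07, with an SD of 0.030, and serve as the background range.

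All 4 pairs form 1 group, and the ratio within an animal is the measurement, so each test set the mean of the 4 pairs against 0. The tool was limma 3.58.1 in R 4.3.3 (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A second count also asked for a mean log2 ratio of at least 1 in size. The ratios of the 2 E16 pairs were set against those of the E18 and P0 pairs in the same way. Gene lists were tested against all other genes with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and fry as alternatives. With an estimated correlation, camera has only the residual degrees of freedom, 3 here and 2 for the stage comparison. It then has little power after adjustment, so a miss need not mean that correlated genes made the call. fry asks whether a list moves on balance one way and does not set it against other genes. The 23 lists were fixed from textbook knowledge before the data were examined, as were the tests and most alternatives. They cover stem cell markers, Wnt, Notch and YAP targets, Paneth, goblet, enteroendocrine, enterocyte and tuft cells, and intestinal transcription factors. Others cover fetal spheroid markers, cell cycle, gastric and squamous epithelium, adhesion and matrix, interferon response, cholesterol synthesis, imprinted growth genes and suckling-stage intestine. Mesenchyme, endothelium, leukocytes and nerve were included as other cell types. Some genes stand in 2 lists, such as Ccn2 and Lgr5.

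Genes were named by a rule fixed beforehand: Lgr5, Gja1 and a further gene that is not reported here, then the 12 highest and 12 lowest mean ratios among genes past the threshold with the same sign in all 4 pairs, without clone or locus names. Up to 4 members per list with the largest moderated t and, for the stage comparison, 3 genes per direction with the largest moderated t were added. Other list members are named only as examples, chosen after their values were seen. Alternatives were scaling columns to the same median absolute deviation, a single probe per gene, a robust prior, array weights, probes in place of genes, a mean of the 3 stage means, other thresholds and leaving out each pair. Inclusion of the control probes, the list tests on the stage comparison and families of genes sharing a symbol stem were added after seeing the data. Centring on the median was not run because the columns lay within 0.01 of 0, and a rule for missing values had nothing to act on.

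The test was checked on simulated ratios with each gene's own spread over 15123 genes and 4 pairs. It recovered 47.4% of genes changed by 0.5 log2 units, 69.8% of those changed by 1 and 87.4% of those changed by 2. Of 738 calls, 49 (6.64%) were false, and 0 of the recovered genes had the wrong sign. For the stage comparison, 121 of 200 genes changed by 2 were recovered, with 10 false calls. In the list step, 0 of 22 unshifted lists were called. Noise was drawn independently for each gene and pair, so genes or pairs that vary together were not simulated. The correlation estimated in the real lists reached 0.86, for cholesterol synthesis. The check therefore cannot show how often camera with the preset correlation calls such lists falsely.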

Results

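Spheroids and organoids grown from the same small intestine were compared on arrays, with 1 ratio per gene and animal. There were 4 animals: 2 fetuses of embryonic day 16 (E16), 1 of embryonic day 18 (E18) and 1 newborn of postnatal day 0 (P0). Organoids carry Lgr5-positive stem cells, and the study asked what sets fetal spheroids apart from them. Each ratio is on the log2 scale with positive values read as higher in spheroids, the likely direction. The share of the 15123 genes with a ratio above 1 in size was 6.16% in the P0 pair, 5.84% and 5.20% in the E16 pairs and 4.50% in the E18 pair.

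The ratios of the 4 animals were alike in part. Across genes, which are not independent replicates, the first and second E16 pairs had a Pearson correlation of 0.916 (Spearman 0.763). The P0 pair correlated with the E16 pairs at 0.650 and 0.585 (Spearman 0.392 and 0.313) and with the E18 pair at 0.622 (Spearman 0.461). The E18 pair correlated least with the E16 pairs, at 0.387 and 0.316 (Spearman 0.176 and 0.112). Of all genes, 30.7% had the same sign in all 4 pairs. Chance gives 12.5% if the 4 pairs are independent, and more where pairs are alike, as the E16 pairs were.

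The gap junction connexin gene Gja1 (Entrez gene 14609) stood highest in spheroids among named genes, 27.1-fold above organoids, with a log2 ratio of 4.76 ± 0.66 (SD, n = 4) and an adjusted p of 0.0130. Ccn2, which encodes connective tissue growth factor, followed at 4.11 ± 0.80, and Sftpd, a secreted collectin of the surfactant, at 3.71 ± 1.14. For Sftpd the P0 pair, at 5.40, lay apart from the other pairs, which lay between 2.92 and 3.30. Also among the 12 highest were the secreted chaperone Clu at 3.53 ± 0.89, the surface protein Msln at 3.45 ± 0.77, the carbonic anhydrase Car2 at 3.63 ± 0.92 and the annexin Anxa1 at 3.25 ± 0.38. The basement membrane collagen Col4a1 had a ratio of 3.19 ± 0.72, the tubulin Tubb6 3.34 ± 0.40, the LIM protein Crip2 3.27 ± 0.25, the membrane proteolipid Mal 3.26 ± 0.74 and the synaptotagmin Syt16 3.30 ± 0.83. Adjusted p of these 12 genes lay between 0.00805 (Crip2) and 0.0423 (Sftpd).

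Among genes past the threshold, the lectin gene Itln1 stood lowest in spheroids, with a log2 ratio of -4.01 ± 1.31. The defensin gene Defa31 had a ratio of -3.62 ± 0.84 and the lysozyme gene Lyz1 one of -3.21 ± 0.76. All 3 are known from Paneth cells. Defensin and lysozyme genes have near-identical copies, so a probe may read more than its own gene. Lgr5 (Entrez gene 14160), the stem cell receptor for R-spondin, was 3.78-fold lower in spheroids, with a log2 ratio of -1.92 ± 0.58 and an adjusted p of 0.0415, and was negative in 4 of 4 pairs. Smoc2, another marker of the crypt base, had a ratio of -2.94 ± 0.92. The brush border peptidase Dpp4 had a ratio of -2.87 ± 0.78, the gluconeogenic enzyme Fbp1 -2.71 ± 0.82, the ornithine aminotransferase Oat -2.62 ± 0.67 and the granule protein Chgb -2.54 ± 0.35. The pyrimidine-degrading enzyme Dpyd stood at -3.34 ± 0.44, Rgcc at -3.28 ± 0.83 and Nrn1 at -2.97 ± 0.71. The linker histone gene H1f10 had a ratio of -3.03 ± 0.93, with the P0 pair at -4.43 and the other pairs between -2.63 and -2.51. Adjusted p of the 12 lowest genes lay between 0.0130 (Dpyd and Chgb) and 0.0462 (Itln1).

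In all, 660 of 15123 genes passed the threshold in limma, 457 higher and 203 lower in spheroids. All 660 had the same sign in the 4 pairs, which passing with 4 pairs all but requires, so it adds no support. At least 2-fold were 256 of them, 177 higher and 79 lower. The counts depended most on the 2 E16 pairs: 145 genes passed without the P0 pair and 2 without the first E16 pair. Without the second E16 pair 0 passed in limma (2346 at an unadjusted p under 0.05). Without the E18 pair 740 passed, of which 379 were among the 660. In the same order, the 2-fold counts were 95, 2, 0 and 313. The test took all 4 animals as independent. The E16 pairs shared a stage and correlated at 0.916, so the count of 660 may be too liberal. The gene count was 395 with 1 probe per gene. It was 1417 with array weights, which were 2.08 and 1.39 for the E16 pairs, 0.63 for P0 and 0.55 for E18. It was 3763 with a mean of the 3 stage means. In that fit the spread came only from the difference between the E16 pairs, so the count is too liberal.

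**Figure D1:**
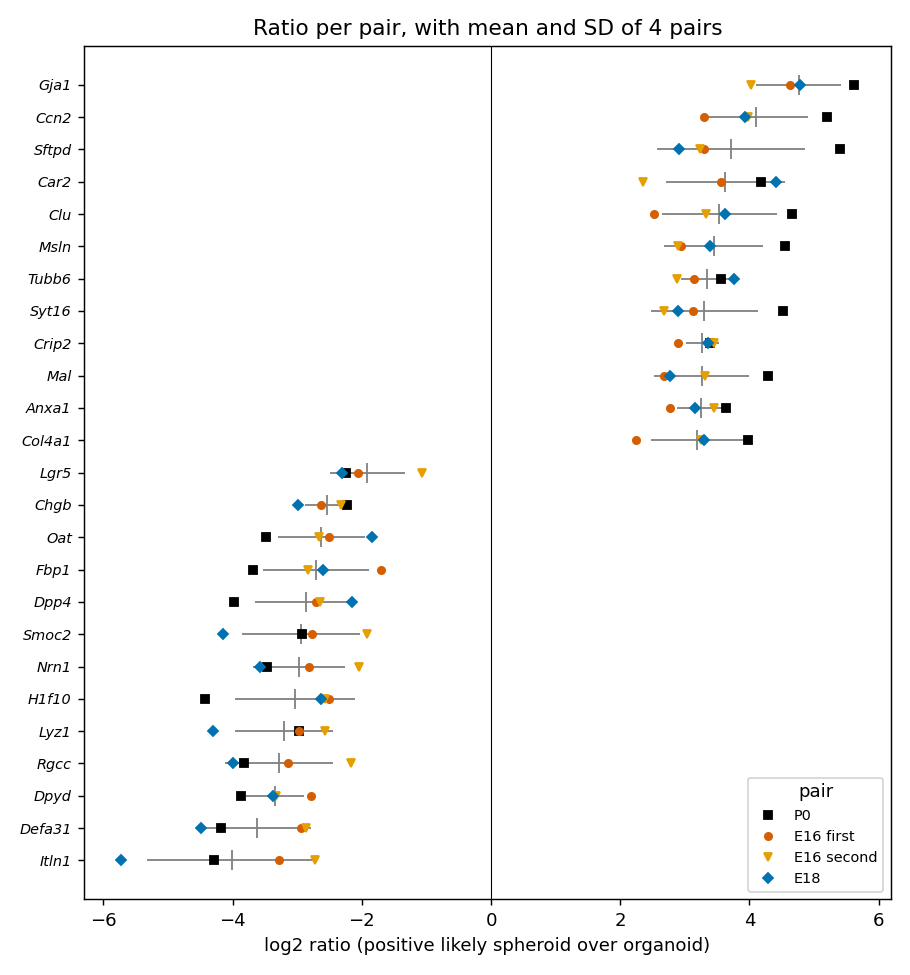
Log2 ratio (x axis, positive likely spheroid over organoid) of Lgr5 and of the 12 highest and 12 lowest genes past the threshold (y axis). Symbols are the 4 pairs, and grey marks and bars are the mean and SD; Gja1 lies between 4.03 and 5.62 in the 4 pairs and Lgr5 between -2.31 and -1.06.

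Genes known from fetal spheroids formed the list with the highest ratios. Of its 15 measured members, 13 passed higher (14 adjusted over the list alone), 0 passed lower, and the median of the mean ratios was 2.82. Besides Gja1 and Anxa1, the keratin Krt7 stood at 2.37 ± 0.053 with an adjusted p of 0.00170, the smallest of all genes, and the interleukin receptor antagonist Il1rn at 2.35 ± 0.27. The list is not independent evidence of direction, since the study picked Gja1 on these samples. camera gave an adjusted p of 6.97e-16, fry an adjusted p of 0.00109, and camera an adjusted p of 0.183 with an estimated correlation.

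Targets of the transcriptional coactivator YAP, squamous epithelium genes and adhesion and matrix genes were also higher in spheroids by camera with the preset correlation. With an estimated correlation these lists did not pass in camera, with adjusted p of 0.532, 0.183 and 0.183. The estimates for the squamous and adhesion lists, -0.006 and -0.027, lay below the preset 0.01. Correlated genes therefore do not account for the misses of the squamous and adhesion lists. Of 18 YAP targets, 4 passed higher (6 adjusted over the list alone, with 1 lower): Ccn2, Ankrd1 at 1.09 ± 0.21, Ptpn14 at 0.55 ± 0.097 and Igfbp3 at 0.51 ± 0.14. Ptpn14 was 0.40 in the E18 pair and between 0.58 and 0.61 in the others. The list's median was 0.40, with an adjusted p of 3.93e-05. Of 18 squamous genes, 4 passed higher (6 adjusted over the list alone). They were the keratin Krt4 at 2.98 ± 0.39, the cornified envelope proteins Lor at 3.05 ± 0.56 and Ivl at 2.47 ± 0.58, and the desmosome-associated Perp at 0.76 ± 0.14. The squamous median was 0.14, with 7 members inside the negative control range; the adjusted p was 0.000282. Of 19 adhesion and matrix genes, 3 passed higher and 1 lower (8 and 1 adjusted over the list alone). Col4a1, Col4a2 at 2.99 ± 0.95 and the laminin chain Lamb3 at 0.94 ± 0.25 were higher, and the integrin Itga6 was lower at -0.28 ± 0.067. That list had a median of 0.46 and an adjusted p of 0.000282. fry called the squamous list (adjusted p = 0.00784) and the adhesion list (adjusted p = 0.0167) but not the YAP targets (adjusted p = 0.0693).

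Markers of the hormone-secreting enteroendocrine cells were lower in spheroids by camera with the preset correlation (adjusted p = 1.14e-10), but not with an estimated correlation (adjusted p = 0.583) or by fry (adjusted p = 0.0696). Of 26 measured, 4 passed lower (13 adjusted over the list alone), 23 were negative in all 4 pairs, and the median was -1.06. The members past the threshold were Chgb, the peptide hormone genes Sct at -1.79 ± 0.39 and Tac1 at -2.35 ± 0.55, and Neurog3, the transcription factor that founds this lineage, at -1.11 ± 0.31. Neurog3 was -1.57 in the E18 pair and between -0.997 and -0.93 in the others.

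Paneth cell genes had a median of -1.46 over 10 measured members, of which 2 passed lower, Lyz1 and Itln1 (6 adjusted over the list alone). Defa3, at -3.99 ± 1.46, and the secreted ribonuclease Ang4, at -3.03 ± 1.20, missed the threshold with adjusted p of 0.0557 and 0.0645. Paneth cells had an adjusted p of 0.000282 in camera, and an adjusted p of 0.532 with an estimated correlation. Stem cell markers had a median of -0.40 over 17 members, of which 3 passed lower (5 lower and 1 higher adjusted over the list alone): Lgr5, Smoc2 and the BMP co-receptor Rgmb at -0.83 ± 0.25. Axin2 missed the threshold at -0.98 ± 0.42, with an adjusted p of 0.0760. The stem cell list had an adjusted p of 0.0106, an adjusted p of 0.745 with an estimated correlation, of 0.163 without the E18 pair and of 0.0749 with array weights.

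Absorptive enterocyte genes had a median of -1.06 over 24 members, and 2 passed lower, also when adjusted over the list alone. They were the sodium-glucose transporter Slc5a1 at -2.40 ± 0.58 and Dpp4. Medians by pair differed, at -1.87 and -2.27 in the E16 pairs, -0.72 in the P0 pair and 0.35 in the E18 pair. camera gave an adjusted p of 0.000271, and an adjusted p of 0.745 with an estimated correlation. Of 19 intestinal transcription factors, 2 passed lower (6 lower and 2 higher adjusted over the list alone). These were the vitamin D receptor Vdr at -1.60 ± 0.39 and the hindgut factor Cdx1 at -1.74 ± 0.47. The orphan receptor Nr5a2, at -0.70 ± 0.30, and the bile acid receptor Nr1h4, at -1.23 ± 0.64, missed the threshold, with adjusted p of 0.0785 and 0.106. This list had a median of -0.40 and an adjusted p of 0.0303. The adjusted p was 0.745 with an estimated correlation, and 0.0572 and 0.112 without the first and the second E16 pair.

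Interferon response genes had a median of -0.47 over 18 members with 0 past the threshold, also when adjusted over the list alone. Ifih1, a sensor of viral RNA, had a log2 ratio of -0.80 ± 0.53, and Ifitm3, a membrane protein that blocks virus entry, -1.91 ± 1.41. Medians by pair ran both ways, at -1.33 in the P0 pair, -0.17 and -0.995 in the E16 pairs and 0.41 in the E18 pair. camera gave an adjusted p of 0.0271, and an adjusted p of 0.861 with an estimated correlation. It was 0.714 without the P0 pair and 0.115 without the second E16 pair.

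In all, camera called 10 of 23 lists, 4 higher and 6 lower, with the preset correlation, 0 with an estimated one and 3 by fry. The other 13 lists did not pass, but single members of some did. Among 16 Wnt targets (median -0.01, mean 0.07), the cyclin Ccnd1 at 2.27 ± 0.57 and the adhesion receptor Cd44 at 0.79 ± 0.10 were higher, and Lgr5 was lower (2 and 2 adjusted over the list alone). Their adjusted p in camera was 0.865, with a positive direction against the negative median. Of 20 Notch genes (median -0.002, mean 0.03, negative direction in camera, adjusted p = 0.865), the ligand Dll1 was lower at -0.97 ± 0.039 and the ligand Jag1 higher at 0.75 ± 0.090 (1 and 1 adjusted over the list alone). Of 17 goblet cell genes, Guca2a, the guanylin precursor, was lower at -2.47 ± 0.81, also over the list alone. The goblet list had a median of -0.23 and an adjusted p of 0.0832. Its adjusted p was 0.000400 without the P0 pair and 0.0269 with array weights.

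Of 29 cell cycle genes (median 0.08, adjusted p = 0.201), the anaphase activator Cdc20 was higher at 0.51 ± 0.15, also over the list alone. The cell cycle list passed without the P0 pair (adjusted p = 0.00810), without the E18 pair (adjusted p = 0.0110) and with array weights (adjusted p = 0.00203). Of 11 imprinted growth genes (median -0.00025, mean -0.02, positive direction in camera, adjusted p = 0.865), Phlda2 was higher at 1.05 ± 0.15, also over the list alone. Of 11 genes of the suckling-stage intestine (median -0.07, adjusted p = 0.366), Amn, part of the intestinal cobalamin receptor, was lower at -1.98 ± 0.14 and the arginine synthesis enzyme Ass1 higher at 0.41 ± 0.12 (2 and 2 adjusted over the list alone). Of 17 cholesterol synthesis genes, 0 passed (median 0.09, adjusted p = 0.366), with 0 over the list alone. This list passed without the first E16 pair (adjusted p = 0.0495) and without the second (adjusted p = 0.0187).

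Markers of other cell types lay near 0 for the most part. Of 20 mesenchyme genes, 18 had a mean inside the range of the negative control probes, as did 11 of 13 endothelial, 8 of 9 neural and 8 of 12 tuft cell genes, and 0 of these lists' members passed, also over each list alone. Tuft cell gene Alox5ap was -1.35 in the P0 pair and between -0.16 and 0.02 in the others. camera gave these lists adjusted p of 0.389, 0.847, 0.668 and 0.847. Among 15 leukocyte genes (median 0.01, adjusted p = 0.622), the lysosomal Laptm5 at 2.58 ± 0.55 and the lipopolysaccharide receptor Cd14 at 2.10 ± 0.65 were higher and the lysozyme Lyz2, a near-copy of Lyz1, lower at -1.71 ± 0.35 (2 and 1 adjusted over the list alone). The other 12 leukocyte genes, Ptprc among them at 0.03 ± 0.038, did not pass. Of 13 gastric epithelium genes, 0 passed (1 adjusted over the list alone), and the list had a median of 0.33 and an adjusted p of 0.0894. Single gastric genes had large ratios with a wide spread: Gkn1 at 2.87 ± 1.05 (adjusted p = 0.0552), Ctse at 3.15 ± 1.54 (adjusted p = 0.0962), Gkn2 at 2.71 ± 2.07 and Tff1 at 2.19 ± 1.98. Each was highest in the P0 pair, where Gkn1 stood at 4.42 against 2.12 to 2.49 in the others.

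**Figure D2:**
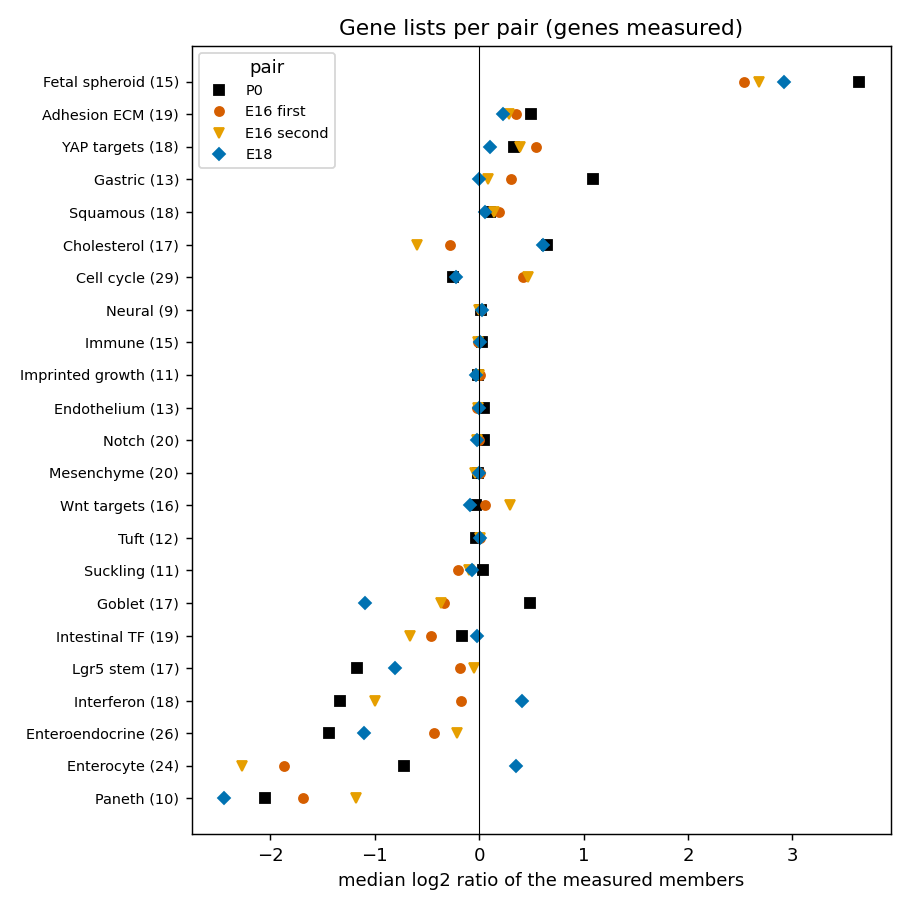
Median log2 ratio (x axis) of the measured members of each of 23 gene lists (y axis, number of measured genes in brackets), with a symbol for each of the 4 pairs. The fetal spheroid list lies between 2.54 and 3.64 in the 4 pairs, and the enterocyte list runs from -2.27 to 0.35.

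The stage comparison asked whether the spheroid to organoid ratio differed between the 2 E16 pairs and the pairs of E18 and P0. By camera with the preset correlation, cell cycle genes had a higher ratio at E16, with a median of 0.43 against -0.26 later (adjusted p = 9.33e-14), and an adjusted p of 0.436 with an estimated correlation. Enteroendocrine genes stood at -0.32 at E16 against -1.42 later (adjusted p = 5.19e-10), with an adjusted p of 0.436 with an estimated correlation. Stem cell markers stood at -0.23 against -0.74 (adjusted p = 8.99e-05) and Wnt targets at 0.22 against -0.04 (adjusted p = 0.00291). With an estimated correlation their adjusted p was 0.522 and 0.587. YAP targets stood at 0.46 against 0.26 (adjusted p = 0.0186) and Paneth cell genes at -1.43 against -1.68 (adjusted p = 0.0193). These lists had adjusted p of 0.683 and 0.497 with an estimated correlation. For Paneth cell genes the median of the members' own differences was larger, at 1.21. The medians at E16 and later need not come from the same member. Cholesterol synthesis genes had a lower ratio at E16, with a median of -0.46 against 0.73 later (adjusted p = 9.12e-11), as did enterocyte genes at -2.07 against -0.20 (adjusted p = 4.54e-07) and intestinal transcription factors at -0.56 against -0.05 (adjusted p = 0.00935). The adjusted p of these 3 lists was 0.436, 0.683 and 0.480 with an estimated correlation. The list tests on this comparison were added after seeing the data, and 0 of these 9 lists passed with an estimated correlation. fry called 0 lists, with a smallest adjusted p of 0.0708. YAP targets missed the threshold without the E18 pair (adjusted p = 0.135) and Paneth cell genes with columns scaled to the same spread (adjusted p = 0.0550). Interferon response genes, which did not pass (adjusted p = 0.956), had a lower ratio at E16 without the P0 pair (adjusted p = 0.00138) and a higher one without the E18 pair (adjusted p = 2.14e-05).

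Members behind these medians missed the threshold adjusted over all genes. Adjusted over the list alone, 19 of 29 cell cycle, 14 of 17 cholesterol synthesis, 12 of 26 enteroendocrine and 6 of 24 enterocyte genes passed. So did 3 of 16 Wnt targets, 2 of 17 stem cell markers, 2 of 10 Paneth cell genes, 2 of 19 transcription factors and 1 of 18 YAP targets. The fatty acid binding protein gene Fabp1 was -2.88 at E16 and -0.29 later, and the vitamin A binding protein gene Rbp2 -2.59 and 0.79. Insig1, a regulator of cholesterol synthesis, was -1.71 at E16 and 0.73 later. Cdc6, which loads the helicase for replication, was 0.74 at E16 and -0.14 later, and the hormone gene Gcg, the glucagon precursor, -1.66 and -5.51. Among all genes, limma called 0 at an adjusted p under 0.05 (2883 at an unadjusted p under 0.05, 1450 higher and 1433 lower at E16, and 509 at an adjusted p under 0.1). The smallest adjusted p was 0.0829. It was shared by the genes with the largest moderated t, which all miss the threshold. Higher at E16 were Slamf9, with a difference of 2.02, and the histone genes H2ac24 (1.46) and H2ac10 (1.38), whose sequences are close copies. Lower at E16 were the isocitrate dehydrogenase Idh1 (-2.47), the peroxisomal thiolase Acaa1a (-1.92) and the RNA-editing enzyme Apobec1 (-1.52). Without the P0 pair 1544 genes passed and without the E18 pair 443, with the lone later pair assumed to vary like the E16 pairs. Stage and any array batch of the E16 pairs cannot be told apart, since no batch is given.

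**Figure D3:**
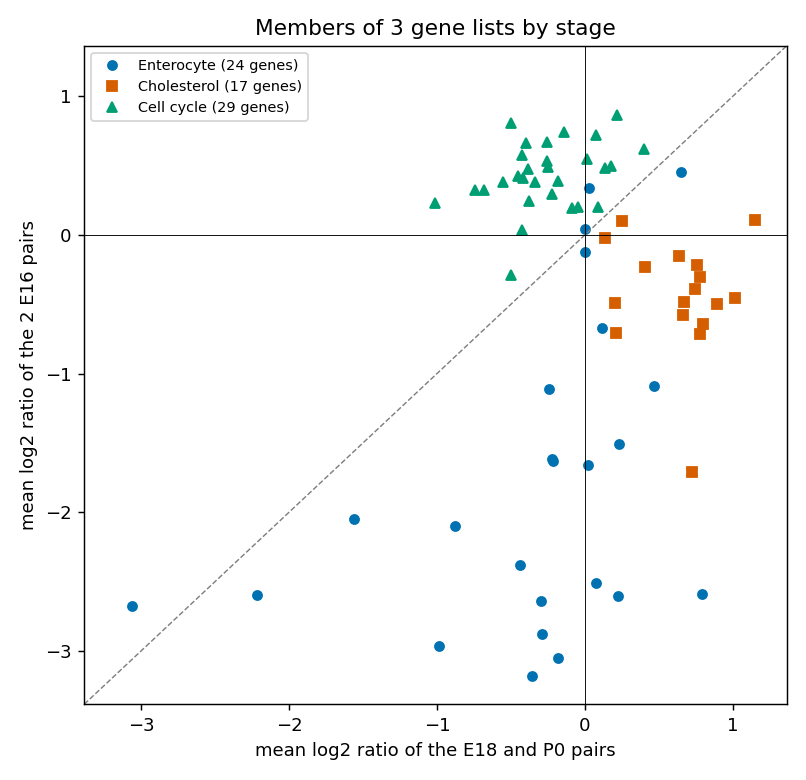
Mean log2 ratio of the 2 E16 pairs (y axis) against that of the E18 and P0 pairs (x axis) for the measured genes of the enterocyte, cholesterol synthesis and cell cycle lists, with a point per gene and a dashed line of equal ratios. Points below the line have a lower ratio at E16, such as Fabp1 at -2.88 against -0.29.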

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

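The tests of the stage difference by list, the scaling of ratios and the cell type explanations were chosen after the results were seen; the counts over other orientations and splits were set before those were run, with the real counts known.

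In the 134 named genes and list medians looked at, the value of 1 pair stood far from the other 3 in 6. Chance would give 6.7 if the values of the pairs were independent and normal. The E16 pairs were alike and most genes were named for a large ratio or moderated t, so that figure is only a rough guide. The P0 pair stood apart for Sftpd (5.40, others 2.92 to 3.30), H1f10 (-4.43, others -2.63 to -2.51), Alox5ap (-1.35, others -0.16 to 0.02) and Gkn1 (4.42, others 2.12 to 2.49). The E18 pair stood apart for Neurog3 (-1.57, others -0.997 to -0.93) and Ptpn14 (0.40, others 0.58 to 0.61).

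Probes without a gene name, used in no comparison of genes, held the most extreme ratios. Probe mMR027206 had a mean log2 ratio of 5.29 ± 1.82 and probe mMR029859 one of -4.43 ± 1.67, against -0.16 to 0.07 for the negative control probes. Both missed the threshold, with adjusted p of 0.0636 and 0.0734. Among 12773 unnamed probes 178 passed in limma, 86 higher and 92 lower in spheroids. The highest and the lowest of these were mMC001687 at 3.87 ± 0.39 and mMC020899 at -4.38 ± 0.76.

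The ratio at E16 differed from that of the later pairs for 9 lists in camera with the preset correlation and for 0 with an estimated one. The median difference, E16 minus later, was 0.75 for stem cell markers, 0.68 for Wnt targets, 1.21 for Paneth cells, 0.88 for enteroendocrine cells, 0.22 for YAP targets and 0.72 for cell cycle genes. It was -1.49 for enterocytes, -0.33 for intestinal transcription factors and -1.09 for cholesterol synthesis.

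A larger overall scale of the ratios in some pairs would keep each gene's sign, and the difference would end once the columns are scaled to the same median absolute deviation. After that scaling, which moved the call of 2 of the 23 lists, the median difference was -1.55 (quartiles -2.42 to -0.53) for enterocytes. It was -1.11 (-1.39 to -0.81) for cholesterol synthesis and 0.72 (0.46 to 0.96) for the cell cycle. All passed in camera with the preset correlation (adjusted p 1.39e-07, 5.14e-11 and 1.99e-13). The median absolute deviations of the columns were already alike, at 0.095 to 0.121 over all probes. The scaling therefore changed the ratios little, so passing after it is weak evidence against scale. The alike spreads themselves leave little difference in scale between the columns. The share of members on opposite sides of the negative control probes in both E16 and both later pairs depended on the range taken. Beyond the lowest and highest probe of each pair it was 17.1% of 70 (exact 95% interval 9.18 to 28.0%), with 4.17%, 52.9% and 6.90% in these lists. Beyond the central 95% of the probes, a range chosen later, it was 35.7% (24.6 to 48.1%), with 12.5%, 52.9% and 44.8%. For cholesterol synthesis the 52.9% (27.8 to 77.0%) in either range argues against scale as the whole cause. For enterocyte and cell cycle genes the first range gave few such members. Cell cycle medians still changed sign, at 0.42 and 0.47 in the E16 pairs, -0.25 in the P0 pair and -0.22 in the E18 pair. Enterocyte medians were -1.87 and -2.27 in the E16 pairs and 0.35 in the E18 pair. In the P0 pair the enterocyte median was -0.72, though that column had the largest median absolute deviation, at 0.121. These medians argue against scale as the whole cause for both lists. An array or labelling batch shared by the E16 pairs could also give such a difference: their correlation of 0.916, against at most 0.650 elsewhere, would follow from a shared stage or a shared batch, and the sources used here give no batch. Of 3 splits of the pairs into 2 and 2, the real split was the 1 with as many genes at an unadjusted p under 0.05 (2883, highest other 329), and 3 splits are too few for a share under 0.05; a change with developmental stage stays open and untested.

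The gastric-type genes Gkn1, Gkn2, Tff1, Tff2 and Ctse had positive mean ratios, from 1.85 to 3.15, and in the P0 pair they lay between 4.42 and 5.64. Parietal and chief cells of the stomach would bring Atp4a, Atp4b, Cblif and Pgc, whose median was -0.15 in the P0 pair (range -0.34 to 1.09) and -0.056 over all pairs, against 2.71 for the gastric-type genes. Pgc gave the highest of these P0 ratios, at 1.09. Brightness over background is unknown, so ratios near 0 speak against these cells only as far as the probes detect the genes. Gastric surface or progenitor cells, carried over or formed in culture, could still be a source. Cldn18, made across gastric epithelium, had a mean of 0.13, above every negative control probe of the pair in 1 of 4 pairs, and Sox2 a mean of -0.01, which does not decide it. An origin in the intestinal epithelium itself was not tested.

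Laptm5 and Cd14, genes known from leukocytes, were higher in spheroids at 2.58 and 2.10. Leukocytes among the spheroid cells would raise other abundant leukocyte genes too, but Ptprc, C1qa, C1qb, C1qc, Tyrobp, Fcer1g and Coro1a had a median mean ratio of 0.011 (range -0.11 to 0.03). Lyz2, abundant in macrophages, was lower at -1.71. Intestinal epithelium also expresses lysozyme, and the Lyz2 probes may read the near-copy Lyz1, so Lyz2 does not bear on this. The leukocyte genes' ratios near 0 argue against leukocytes as the source of both ratios only as far as their probes detect these genes. Brightness over background is unknown, and these ratios lay inside the negative control range. A hypothesis left open is that the spheroid epithelium itself may express both genes; it was not tested, and the median of 0.011 bears only on leukocytes.

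Turning spheroid and organoid round in some of the pairs gives 8 orientations, too few for a share under 0.05. The real orientation was the 1 with as large a count for genes (660, highest other 0), for genes at least 2-fold apart (256, highest other 0) and for lists (10, highest other 8). All columns correlated positively with each other, so turning a pair was bound to lower the gene counts, which adds no support.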

How the results depend on the processing

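Each test is already paired, since each ratio is taken within an animal. The control probe setting, the thresholds for the stage count and the settings of the stage list test were chosen after seeing the data. Scaling columns to the same median absolute deviation, a robust prior, probes in place of genes and inclusion of control probes kept the gene counts within 1.5 times. The count of 660 genes moved to 395 with 1 probe per gene, 1417 with array weights, 3763 with a mean of the 3 stage means, 25 at a threshold of 0.01 and 1381 at 0.1. The 256 genes at least 2-fold apart became 413 with array weights and 568 with the mean of stage means. Both settings lean on the E16 pairs, which had the highest weights and gave the only spread around the stage means. Without each pair in turn, the counts ran from 0 to 740 and, at least 2-fold apart, from 0 to 313; both were lowest without the second E16 pair (2346 genes at an unadjusted p under 0.05 in limma). The cause was not tested. The 10 lists became 0 with an estimated correlation and 3 with fry, and ran from 9 to 11 without each pair. The 9 lists of the stage test became 0 with an estimated correlation and 0 with fry, and stayed at 9 with scaled columns, where Paneth cells no longer passed and fetal spheroid genes did. They ran from 10 to 12 without the P0 or E18 pair. Interferon response genes were added as lower at E16 without the P0 pair (adjusted p 0.00138) and as higher without the E18 pair (adjusted p 2.14e-05). Without the E18 pair goblet, fetal spheroid and gastric genes were also added and YAP targets lost. The stage count of 0 genes ran from 443 to 1544 without a later pair, was 509 at a threshold of 0.1 and stayed at 0 at a threshold of 0.01, with scaled columns, 1 probe per gene, a robust prior, array weights and the 3 embryonic pairs against P0. The mean of the 6 correlations was 0.579, and 0.586 over genes above the median in size. Among the 10 lists that differed between spheroids and organoids 0 directions turned. Of the 56 named genes past the threshold, 34 missed it without the P0 pair, 55 and 56 without the first and second E16 pair and 22 without the E18 pair. The robust prior was not run for lists. Brightness over background is unknown, so a ratio near 0 can be a gene below detection in both cultures.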

Other observations

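The family search by symbol and its tests were chosen after seeing the data. All 244 groups of at least 8 genes that share the letters of their symbol were tested with camera, and 7 passed with the preset correlation, all higher in spheroids, and 0 with an estimated one. Subunits of the proteasome cap (Psmd) had a median of 0.31, and 5 of 13 passed higher with 0 lower, such as Psmd12 at 0.54 ± 0.069 and Psmd8 at 0.50 ± 0.15 (adjusted p of the family 6.55e-07, and 0.974 with an estimated correlation). Annexins, which bind membranes in a calcium-dependent way, had a median of 0.84, and 6 of 12 passed higher. Besides the fetal spheroid genes Anxa1, Anxa3 and Anxa8 these were Anxa5 at 1.24 ± 0.12, Anxa2 at 0.92 ± 0.26 and Anxa6 at 0.76 ± 0.24 (adjusted p 0.000781, and 0.974 with an estimated correlation). Keratins had a median of 0.04, with 5 of 39 higher, among them Krt18 at 1.44 ± 0.21 and Krt23 at 1.09 ± 0.25 (adjusted p 0.00456, and 0.974 with an estimated correlation). Of the 7 families, 3 passed after scaling of the columns, with 0 directions turned.

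Between stages, 29 families passed, 17 with a higher and 12 with a lower ratio at E16 by the preset correlation, and 0 with an estimated one. The Mcm genes, most of which form the replicative helicase, had a median of 0.43 at E16 and -0.40 later (adjusted p 5.72e-05, and 0.899 with an estimated correlation), and ribosomal proteins of the large subunit (Rpl) 0.06 and -0.25 (adjusted p 0.000235, and 0.901 with an estimated correlation). The glucuronosyltransferases of the Ugt family, which conjugate bile pigments and drugs, had a median of -0.72 at E16 and 0.19 later (adjusted p 2.09e-05, and 0.899 with an estimated correlation). After scaling 28 of the 29 passed with 0 directions turned.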
